A study of Homo sapiens with 95 samples.

How the data were processed

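RNA from kidney transplant biopsies stored as formalin-fixed, paraffin-embedded (FFPE) tissue was measured on the nCounter platform, which counts colour-coded probes bound to RNA without amplification, with a panel of WNT pathway genes and added targets. Per the labels, RNA was taken from sections with a Qiagen kit for FFPE tissue, and the maker's protocol for the panel was followed. The deposited table holds 210 genes in 95 samples, with 1 missing value. The deposited values are signal values on a linear scale, probe counts normalized by the authors in a way not given in the sources used here. They run from 0.53 to 843158. None of the common reference genes looked for (among them GAPDH, ACTB and GUSB) was in the table, so no scaling to such genes was tried. Of the symbols, 205 matched the reference gene table (assembly GRCh38.p14, used for names only) and 5 matched as older symbols. Symbols are printed as deposited, so PPAP2B stands for the gene now called PLPP3.

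Groups came from the diagnosis label of each sample: 25 ABMR, 24 TG and 46 Stable samples. ABMR and TG were pooled as MVI (microvascular injury), 49 samples. The series text counts 50 MVI and 45 Stable samples, 1 apart from the labels, and the labels were followed. A pair of samples carried a title that repeated another sample's title with a suffix. Each was averaged on the log2 scale with the sample it repeats, which left 93 biopsies: 24 ABMR, 24 TG and 45 Stable. The repeats resembled their first run. The median absolute log2 difference over genes was 0.112 in the ABMR pair and 0.110 in the Stable pair. In other pairs of the same group it was at least 0.263 and 0.266. As described below, some of the columns appear to have been scaled gene by gene on these same repeats. That scaling favours their agreement, so these values do not measure repeatability. The labels do not say whether every biopsy came from a different recipient, so p-values measure the spread between these biopsies.

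The values showed 2 sets of columns that the labels do not name. In the last 48 columns, 95 to 100% of the 60 lowest values of a column were whole multiples of 1 step, within a tolerance of 0.0075, where at most 2.99% would be by chance. That gave total counts of 13247 to 434251 per sample, with a median of 180041. Values of exactly 1 occurred 15 times there. In the first 47 columns at most 50% of values were whole multiples, so their depth is unknown. For 209 of 210 genes the sum over the 2 first runs matched the sum over their second runs within 0.1%, against at most 2 genes in 100 other pairings, so the first set appears to have been scaled gene by gene on the repeated biopsies. ABMR fell 12 and 13 into the first and the second set, TG 16 and 8, and Stable 19 and 27. Only sums of normalized counts are known for all samples, from 109724 to 1354822. Precision was therefore taken from the spread between biopsies, and no counting interval is given.

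Values were taken as log2(value + 1), and fold changes are on that scale, which understates the change of low genes; 20 genes had a mean under 20 normalized counts. No gene was filtered out. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) compared MVI with Stable in a fit with 2 groups, and ABMR with Stable, TG with Stable and ABMR with TG in a fit with 3 groups that share the estimate of the spread. P-values were adjusted by Benjamini-Hochberg over 210 genes, with a threshold of 0.05; the series text also names a false discovery rate of 5%. All tests were two-sided. The set was entered as a covariate in further fits, with a biopsy run in both sets coded 1.5, and each set was also fitted alone. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

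Before the data were examined, 14 gene lists were fixed, of which 11 had at least 3 measured members: WNT ligands, Frizzled receptors and co-receptors, WNT inhibitors, the β-catenin destruction complex and its feedback, TCF/LEF factors and nuclear partners, β-catenin/TCF target genes, the planar cell polarity arm, the WNT/calcium arm, endothelial genes, kidney epithelium markers, and fibroblast and matrix genes. Lists of natural killer and interferon-γ-inducible genes had 0 measured members, and the list of T cell, B cell and myeloid markers had 1 (CXCR4), so these were not tested. Lists were tested with fry in limma, which asks whether a list's genes move one way on balance, adjusted over the 11 lists of a comparison. Alternatives were camera with its preset correlation of 0.01 and with an estimated correlation. Camera asks another question, whether a list's genes move more than the other genes of the panel. Every adjusted p given below with an estimated correlation is from camera. Genes to name were also fixed beforehand: the 10 largest changes in each direction past the threshold for MVI against Stable and for ABMR against TG, the 6 largest in each direction for ABMR and for TG against Stable, and the 3 members of each list with the smallest p in MVI against Stable (and in ABMR against TG where the list passed there). One gene that this rule picks is not reported here by name, though it stays in the counts over all genes and lists.

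The fit was tested on simulated data with 40 of 210 genes changed, in 20 simulations. For MVI against Stable it recovered 79.25% of changes of 0.5 and 97.5% of changes of 1 on the log2 scale, and 4.07% of its calls were false. For ABMR against Stable it recovered 67.25% and 94.25%, for TG against Stable 72% and 95%, and for ABMR against TG 57.75% and 90.25%. False calls made up 5.69% of the calls for ABMR against Stable, 4.02% for TG against Stable and 6.48% for ABMR against TG. A simulated shift of 1 list was called in 20 of 20 simulations, and other lists in 3 of 160 tests. These simulations shuffled the biopsies over groups and sets and built in no shift of whole samples between groups. The simulated gene changes were as often up as down. The shares of false calls therefore do not measure errors from scaling or from the sets. Alternatives fixed beforehand covered repeated samples, re-centring each sample on its median, quantile normalization, log2(value + 8), leaving out the genes lowest in mean expression, a Wilcoxon rank-sum test, robust limma with sample weights, blocks of 12 columns in deposit order, and the samples in the fit. Those on the sets, quantile normalization and re-centred camera for the lists, and those on the TG library highest in COL1A2 and on second-set libraries under 30000 counts were added after seeing the data. Tests that need raw counts were not run, because the values are normalized.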

Results

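The biopsies were compared to ask how WNT pathway expression differs in kidney transplants with microvascular injury (MVI), defined in the series text by a sum of the g and ptc scores (glomerulitis and peritubular capillaritis) of at least 2, from transplants without it. Normalized counts of 210 genes, 180 of the WNT pathway and 30 added targets per the series text, were available for 93 biopsies after repeats were averaged. These were 24 biopsies labelled ABMR (the usual abbreviation of antibody-mediated rejection), 24 labelled TG (transplant glomerulopathy, a chronic lesion of the glomerular capillaries) and 45 Stable biopsies without major abnormalities. Sample medians ranged from 181.8 to 355.5 normalized counts. Total counts could be recovered for the second set of columns only, where they ran from 13247 to 434251.

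RAC2, PRKCB, CXCR4, PLAUR, VWF and SELE were higher in MVI biopsies than in Stable biopsies, and SOST, FLT1, KDR and LRP6 were lower. RAC2, a small GTPase of blood cells, was 3.16-fold higher (log2 difference 1.66 ± 0.18, SE; 48 MVI and 45 Stable biopsies), with 45 of 48 MVI biopsies above the Stable mean. PRKCB, a protein kinase C abundant in B cells and myeloid cells, was 2.89-fold higher, and the chemokine receptor CXCR4 2.26-fold higher. SOST, which encodes the WNT antagonist sclerostin, was 2.56-fold lower (-1.35 ± 0.26), with 41 of 48 MVI biopsies below the Stable mean. In all, limma called 86 genes at an adjusted p under 0.05, 54 higher and 32 lower in MVI, and 11 of them differed at least 2-fold.

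Other large rises were in the urokinase receptor PLAUR (1.20 ± 0.19), the matrix proteases MMP9 (1.14 ± 0.30) and MMP7 (1.01 ± 0.28), the Toll-like receptor TLR2 (1.10 ± 0.14) and the T cell factor TCF7 (1.06 ± 0.20). Lower in MVI were CAMK2B (-0.63 ± 0.19), CXXC4, an inhibitor of Dishevelled (-0.60 ± 0.15), the oxidase NOX4 (-0.47 ± 0.16), the lipid phosphatase PPAP2B (-0.41 ± 0.11) and RAC3 (-0.38 ± 0.13). VEGFA (-0.49 ± 0.11) and its receptor FLT1 (-0.58 ± 0.11) were both lower, with FLT1 below the Stable mean in 42 of 48 MVI biopsies.

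**Figure D1:**
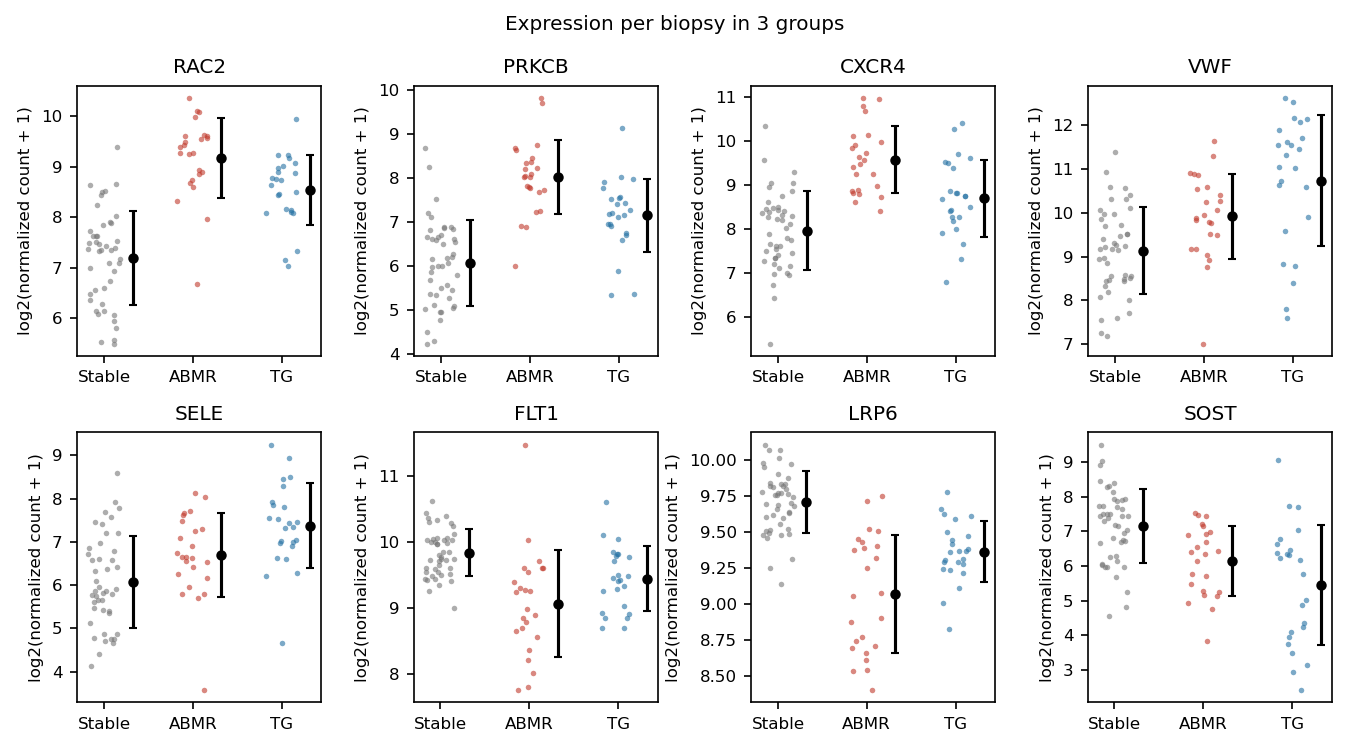
Expression of 8 genes per biopsy as log2(normalized count + 1) in Stable (n = 45), ABMR (n = 24) and TG (n = 24) biopsies; each small point is a biopsy, and black points with bars are the mean and SD. RAC2 lies at 7.20 ± 0.93 in Stable, 9.18 ± 0.79 in ABMR and 8.54 ± 0.69 in TG, while SOST falls from 7.16 ± 1.08 in Stable to 6.15 ± 1.0 in ABMR and 5.46 ± 1.72 in TG.

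Among WNT ligands, 3 of 18 rose and 1 fell in MVI. WNT10B rose by 0.83 ± 0.16, WNT7A by 0.97 ± 0.24 and WNT10A by 0.66 ± 0.18. WNT7A and WNT10B were low, with geometric means of 16.3 and 17.1 normalized counts in Stable. Of 13 Frizzled receptors and co-receptors, 4 fell and 1 rose. The co-receptor LRP6 was lower in MVI (-0.49 ± 0.06, limma adjusted p = 3.3e-10), with 45 of 48 MVI biopsies below the Stable mean. FZD4 was lower by a log2 difference of -0.33 ± 0.07, whereas FZD2 rose by 0.49 ± 0.12. The list as a group moved down by fry (adjusted p = 0.00290). By camera its adjusted p was 0.0977 with the preset correlation and 0.638 with an estimated correlation. Of 12 secreted and membrane inhibitors 2 fell, SOST and WIF1 (-0.50 ± 0.18), and KREMEN1 did not pass (-0.16 ± 0.08, adjusted p = 0.102; 0.0387 without 1 TG library, the highest in COL1A2). The list did not pass (0.0855).

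Of 37 β-catenin/TCF target genes, 15 rose and 2 fell, and the list moved up by fry (adjusted p = 0.00145). By camera its adjusted p was 0.188 with the preset correlation and 0.638 with an estimated correlation. CCND3, a D-type cyclin, was higher by 0.63 ± 0.08 and lay above the Stable mean in 46 of 48 MVI biopsies. The hyaluronan receptor CD44 rose by 0.85 ± 0.15. Several members, such as PLAUR, MMP9, CD44 and TCF7, are also abundant in leukocytes. Among the 20 members that limma did not call were AXIN2 (0.18, adjusted p = 0.222), NKD1 (-0.22, 0.209) and DKK1 (-0.02, 0.940). LEF1 passed as deposited (0.39, adjusted p = 0.0375) but not after re-centring (0.182). In the WNT/calcium arm 4 of 13 rose, including PRKCB, the calcineurin subunit PPP3CC (0.46 ± 0.10) and NFATC1 (0.56 ± 0.10), and 2 fell (fry adjusted p = 0.00232; adjusted p = 0.638 with an estimated correlation). In the destruction complex list 3 of 20 rose, among them CUL1 (0.23 ± 0.04) and FRAT1 (0.61 ± 0.12), and 7 fell (0.0855), against 1 and 15 after re-centring. TCF/LEF factors and partners split into 2 that rose and 2 that fell of 14, the latter BCL9 (-0.30 ± 0.06) and PYGO1 (-0.34 ± 0.13; 0.474 for the list, whose mean was 0.04 and test direction down). After re-centring 1 rose and 7 fell. In the planar cell polarity arm 3 of 13 rose, RAC2, RAC1 and RHOA (0.35 ± 0.08), and 5 fell, among them MAPK8 (-0.23 ± 0.06; 0.991 for the list, whose median was -0.12, mean 0.06 and test direction down). After re-centring 2 rose and 8 fell, and RAC1 was no longer called (-0.003, adjusted p = 0.986). For WNT ligands the re-centred counts were 3 and 2, for inhibitors 0 and 4 and for the WNT/calcium arm 3 and 2.

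Of 9 endothelial genes, 5 rose and 2 fell in MVI as deposited, and 3 rose and 3 fell after re-centring, where ENG and EDN1 no longer passed. VWF, the von Willebrand factor stored in endothelial cells, rose by 1.19 ± 0.24 and SELE, the adhesion molecule E-selectin, by 0.95 ± 0.21, while the VEGF receptors FLT1 and KDR fell (KDR -0.37 ± 0.10). The list had no direction past the threshold (0.119). Of 12 fibroblast and matrix genes 4 rose, among them TGFB1 (0.85 ± 0.13), TIMP1 (0.66 ± 0.20) and TGFBR2, and none fell, against 3 and 3 after re-centring (0.0209; adjusted p = 0.638 with an estimated correlation). The collagen gene COL1A2 was not among those called. All 3 measured kidney epithelium and injury markers moved, VIM (0.70 ± 0.14) and MMP7 up and the epithelial cadherin CDH1 down (-0.33 ± 0.12). The list did not pass (0.0855) but did by fry without 1 TG library, the highest in COL1A2 (0.00521). With an estimated correlation and all libraries its adjusted p was 0.638. Adjusted over the list alone, the counts up and down were 16 and 2 for target genes, 0 and 1 for inhibitors, 1 and 2 for TCF/LEF factors, and as above for the others.

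**Figure D2:**
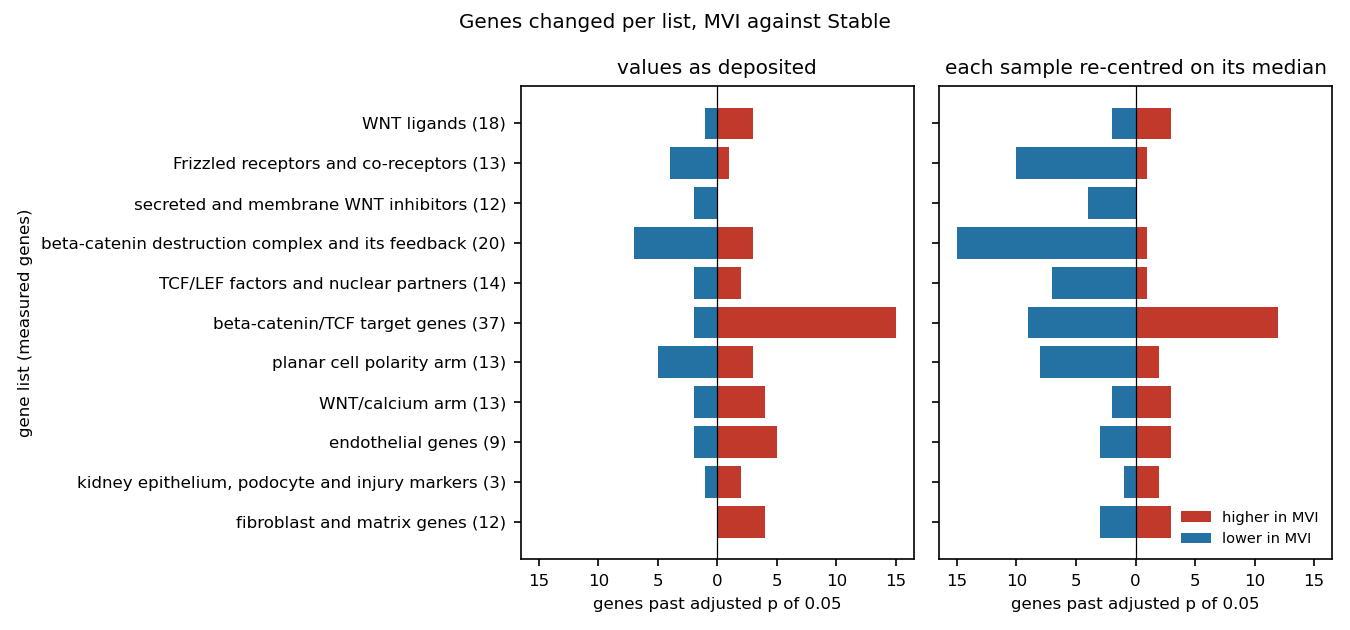
Genes per fixed list past an adjusted p of 0.05 that were higher (right) or lower (left) in MVI than in Stable, with the number of measured genes in brackets; left panel, values as deposited, and right panel, each sample re-centred on its median. Of 37 target genes 15 were higher and 2 lower as deposited, and 12 and 9 after re-centring; of 13 Frizzled receptors and co-receptors 1 was higher and 4 lower, and 1 and 10 after re-centring.

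The balance of rises and falls depended on scaling. Sample medians were higher in MVI by 0.16 on the log2 scale; with each sample re-centred on its median 117 genes were called, 39 higher and 78 lower, and the calls of the WNT/calcium (adjusted p = 0.349) and matrix lists (0.520) ended, as did that of CUL1. In turn, 4 lists that did not pass as deposited were called down by fry after re-centring: inhibitors (adjusted p = 5.1e-05), the destruction complex (5.3e-06), TCF/LEF factors (1.9e-07) and the planar cell polarity arm (0.00230). With an estimated correlation and re-centring none of the 11 lists passed in MVI, these 4 at adjusted p = 0.514, 0.491, 0.491 and 0.650. Quantile normalization also called these 4 down by fry, but kept the calls of the WNT/calcium (0.0462) and matrix lists (0.0139). With an estimated correlation and quantile normalization the planar cell polarity arm had an adjusted p = 0.508, and the others just named 0.456 each. With the set as a covariate 84 genes were called, and WIF1 no longer passed (-0.37, adjusted p = 0.0679). The direction of all 86 genes was the same in each set alone, where 30 and 71 genes were called: RAC2 differed by 1.62 in the first set and 1.83 in the second, SOST by -1.73 and -1.10, and VWF by 0.63 and 1.82. Named genes that limma did not call in the first set alone included VWF (adjusted p = 0.214), SELE (0.123), MMP7 (0.132) and TIMP1 (0.154). WIF1, NOX4, PYGO1 and CDH1 were called in neither set alone.

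**Figure D3:**
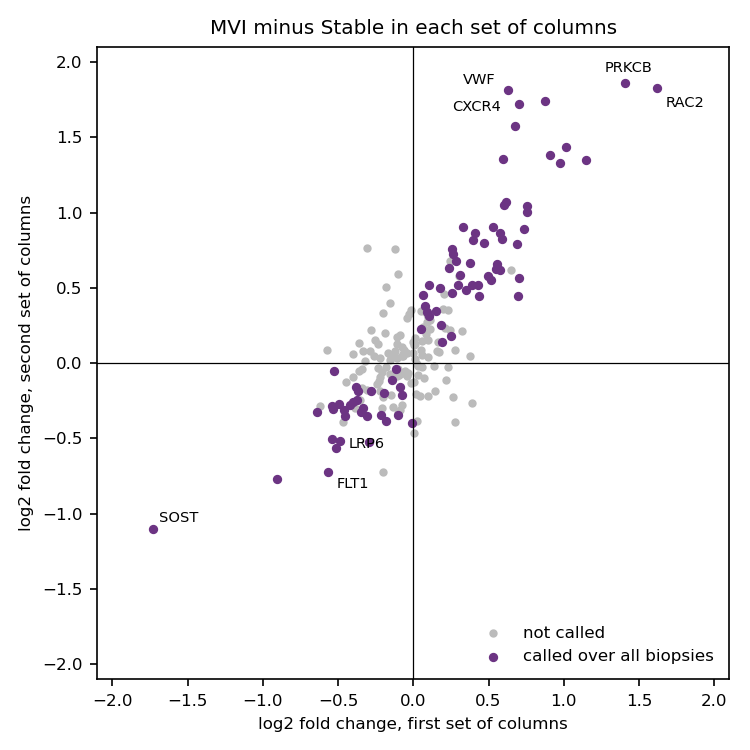
Log2 difference MVI minus Stable per gene in the first set of columns (x axis; 28 MVI and 19 Stable biopsies) against that in the second set (y axis; 21 MVI and 27 Stable), with the 86 genes called over all biopsies in purple. All 86 lie on the same side of 0 in both sets.

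Among the largest rises in ABMR biopsies against Stable ones were those of RAC2 (3.95-fold, 1.98 ± 0.21), PRKCB (3.89-fold, 1.96 ± 0.23) and CXCR4 (3.06-fold), with CXCR4 above the Stable mean in 24 of 24 ABMR biopsies. PLAUR was 2.68-fold and MMP7 2.65-fold higher. SOST (-1.01 ± 0.31), CAMK2B (-0.88 ± 0.22), CXXC4 (-0.84 ± 0.18), the growth factor IGF2 (-0.78 ± 0.32), FLT1 (-0.77 ± 0.14) and WNT9B (-0.68 ± 0.25) were lower. The calls of IGF2 (adjusted p = 0.0694) and WNT9B (0.0927) ended with a Wilcoxon rank-sum test, and that of IGF2 also with robust limma (0.147), with blocks of 12 columns (0.0762) and without libraries under 30000 counts (0.0619). Limma called 88 genes, 49 higher and 39 lower. Frizzled receptors and co-receptors moved down (4 of 13 fell, 1 rose; fry adjusted p = 6.3e-05), as did inhibitors (2 of 12 fell; 0.0107) and the destruction complex (7 of 20 fell, 3 rose; 0.00745), and target genes (14 of 37 rose, 3 fell; 0.00487) and the WNT/calcium arm (4 of 13 rose, 2 fell; 0.00487) moved up. Each of these lists had an adjusted p = 0.551 with an estimated correlation; adjusted over the list alone, 8 genes of the destruction complex fell and the other counts were as given. After re-centring 1 Frizzled list gene rose and 9 fell, 0 inhibitors rose and 5 fell, 1 destruction complex gene rose and 14 fell, 10 target genes rose and 7 fell, and 3 WNT/calcium genes rose and 2 fell. Sample medians were higher by 0.13, and re-centring gave 33 genes higher and 69 lower, and called TCF/LEF factors (1.7e-06), the planar cell polarity arm (0.00966) and endothelial genes (0.0125) down and the epithelium and injury markers (0.0400) up by fry. With an estimated correlation and re-centring these 4 had adjusted p = 0.434, 0.683, 0.683 and 0.434. Within the first and the second set 57 and 76 genes were called, and 87 of the 88 kept their direction in both. Limma did not call IGF2 in the first set alone (-0.22, adjusted p = 0.786). Nor did it call SOST (-0.56, 0.276) and WNT9B (-0.52, 0.202) in the second set alone. With the set as a covariate 90 genes were called.

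The largest rise in TG biopsies was in the endothelial gene VWF. It was 3.03-fold higher than in Stable biopsies (1.60 ± 0.28), SELE 2.45-fold (1.29 ± 0.25; above the Stable mean in 23 of 24) and WNT7A 2.31-fold. RAC2 (2.53-fold), PRKCB (2.14-fold) and PLAUR (1.97-fold) were higher as well. SOST was 3.25-fold lower (-1.70 ± 0.31, below the Stable mean in 21 of 24), followed by VEGFA (-0.42 ± 0.13), FLT1 (-0.39 ± 0.14), WNT3 (-0.38 ± 0.14), ERBB2 (-0.38 ± 0.10) and LRP6 (-0.34 ± 0.07). Limma called 51 genes, 44 higher and 7 lower. Of 9 endothelial genes 6 rose and 1 fell (fry adjusted p = 9.7e-04; adjusted p = 0.714 with an estimated correlation). Target genes (10 of 37 rose, 1 fell; 0.00877), the WNT/calcium arm (3 of 13 rose; 0.0323) and matrix genes (2 of 12 rose; 0.0383) moved up as deposited, each at an adjusted p = 0.745 with an estimated correlation, and none of these 3 passed after re-centring; counts adjusted over the list alone were those given for these 4 lists. After re-centring 4 endothelial genes rose and 2 fell, 5 target genes rose and 3 fell, 2 WNT/calcium genes rose and 2 fell, and 1 matrix gene rose and 1 fell. Quantile normalization kept the calls of target genes (fry adjusted p = 0.0174) and matrix genes (0.0421), each at 0.387 with an estimated correlation. It did not keep that of the WNT/calcium arm (fry adjusted p = 0.620). Without 1 TG library, the highest in COL1A2, the WNT/calcium (0.0600) and matrix lists (0.125) did not pass, nor did they with the set as a covariate (0.0567 each). Sample medians were higher by 0.19, and re-centring gave 27 genes higher and 51 lower, and called Frizzled receptors and co-receptors (0.00102), inhibitors (0.0213), the destruction complex (5.2e-04), TCF/LEF factors (1.3e-04) and the planar cell polarity arm (0.0213) down by fry. With an estimated correlation and re-centring these 5 had adjusted p = 0.478, 0.609, 0.478, 0.478 and 0.609. Within the first and the second set 2 and 28 genes were called, all 51 kept their direction in both, and WNT3 was not called with the set as a covariate (adjusted p = 0.110). In the first set alone limma did not call VWF (0.90, adjusted p = 0.216), SELE (1.24, 0.0785) or WNT7A (0.81, 0.268). Nor did it call PRKCB (1.06, 0.0785), PLAUR (0.87, 0.111) or LRP6 (-0.31, 0.0941) there. The falls of VEGFA, FLT1, WNT3 and ERBB2 were called in neither set alone. Their adjusted p in the first and second set was 0.165 and 0.211 for VEGFA, and 0.205 and 0.107 for FLT1. It was 0.371 and 0.183 for WNT3, and 0.188 and 0.164 for ERBB2.

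The fold changes of ABMR and TG correlated across 209 genes (r = 0.758), which are not independent replicates and share the Stable biopsies. Simulated unchanged groups against the same controls gave a median r of 0.359, and the central 95% of simulations reached up to 0.676. The covariance was 0.147 against 0.0097 simulated, and with the controls split into 22 and 23 biopsies the median r was 0.666. Of the calls, 33 were higher in both, where independent lists would share 10.3, and 6 lower in both against 1.3; part of either excess may come from the shared controls.

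ABMR and TG were then compared directly, which also tests whether their effects against Stable differ. BIRC5, which encodes the mitotic protein survivin, was 2.02-fold higher in ABMR (1.01 ± 0.30), followed by CXCR4 (0.87 ± 0.25), PRKCB (0.86 ± 0.26), TLR2 (0.61 ± 0.19), the haem oxygenase HMOX1 (0.54 ± 0.19), CEBPD (0.48 ± 0.15), FRAT1 (0.47 ± 0.15), PPP3CC (0.38 ± 0.13) and CCND3 (0.30 ± 0.10). FRZB, a secreted WNT antagonist, was 2.01-fold higher in TG (ABMR minus TG -1.01 ± 0.23), with 21 of 24 ABMR biopsies below the TG mean. FGF7, the WNT antagonist DKK3, WNT2B, SOX17, ENG, the Notch ligand JAG1, PPAP2B, VEGFC and KDR were also higher in TG, by differences from -0.80 (FGF7) to -0.45 (KDR). Limma called 24 genes, 9 higher in ABMR and 15 higher in TG.

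Of 9 endothelial genes, 4 were lower in ABMR than in TG: the endothelial co-receptor ENG (-0.59 ± 0.13), the transcription factor SOX17 (-0.59 ± 0.20), KDR (-0.45 ± 0.13) and BMPR2 (-0.28 ± 0.09). After re-centring only ENG of these was called, with SOX17 at an adjusted p = 0.0620, KDR at 0.0796 and BMPR2 at 0.0502, and the list still passed with fry (8.1e-05; adjusted p = 0.0378 with an estimated correlation). As deposited the list passed with fry (adjusted p = 1.2e-04) and with the preset correlation (9.5e-04), but not otherwise (adjusted p = 0.175 with an estimated correlation), and 7 members passed adjusted over the list alone. Frizzled receptors and co-receptors (fry adjusted p = 0.0169), the destruction complex and TCF/LEF factors (0.0445 each) were lower in ABMR as deposited, and not after re-centring; each had an adjusted p = 0.737 with an estimated correlation. Adjusted over the list alone, 3 Frizzled list genes, 0 of the destruction complex (1 over all genes, FRAT1) and 2 TCF/LEF genes passed; at an unadjusted p under 0.05, limma called 58 of the 210 genes. FZD4 (-0.36 ± 0.10), LRP6 (-0.29 ± 0.08) and TCF7L1 (-0.42 ± 0.10) passed as deposited, FZD4 (adjusted p = 0.0817) and LRP6 (0.158) not after re-centring, and FZD7 (-0.45 ± 0.16, adjusted p = 0.0639), DVL1 (-0.20 ± 0.08), CXXC4 (-0.47 ± 0.20) and CREBBP (-0.22 ± 0.09) did not. Without 1 TG library, the highest in COL1A2, the destruction complex and TCF/LEF lists did not pass (0.0745 each), nor did CCND3 (0.0506), FRAT1 (0.0506), FGF7 (0.0686) and HMOX1 (0.0686), while CXXC4 did (0.0404). Apart from the fits of each set alone, 8 of 23 named genes past the threshold kept their call under every alternative run for them. For CXCR4, PRKCB, FRZB, WNT2B, ENG, JAG1 and TCF7L1 these were 13, and for BIRC5 12, since leaving out the lowest genes removes it. With the set as a covariate 25 genes were called, and inhibitors (0.0485) and the planar cell polarity arm (0.0451) also passed as lower in ABMR by fry, each at an adjusted p = 0.692 with an estimated correlation. SOX17 (-0.49, adjusted p = 0.0718) and PPP3CC (0.37, adjusted p = 0.0603) did not pass with the set as a covariate. There were 17 and 4 calls within the first and the second set, with the direction of all 24 the same in both. All of the 8 kept calls but FRZB fell short in the second set alone.

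**Figure D4:**
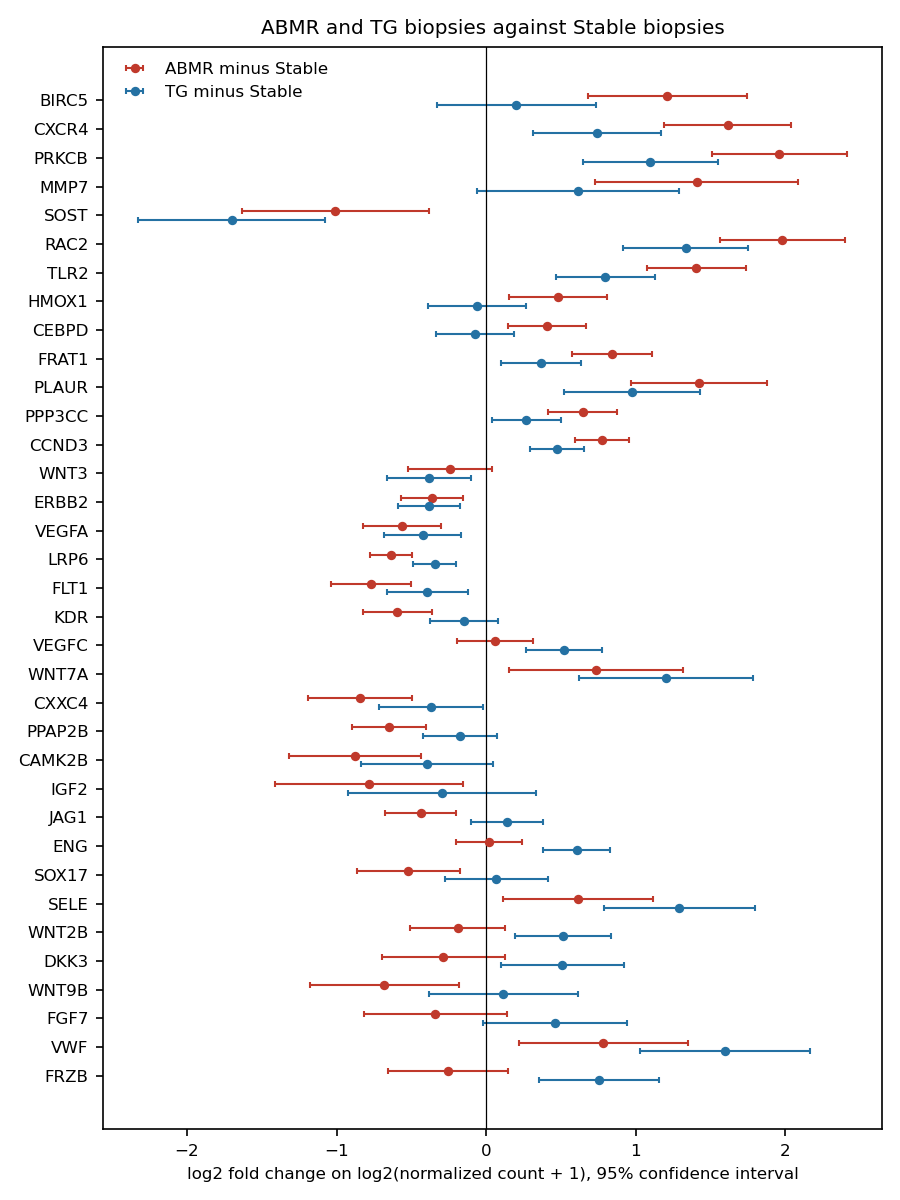
Log2 difference from Stable, with 95% confidence intervals, in ABMR (red, n = 24) and TG (blue, n = 24) for the named genes with the largest changes in the comparisons of ABMR and TG, sorted by the difference between ABMR and TG. BIRC5, at the top, is 1.01 higher in ABMR than in TG, and FRZB, at the bottom, differs by -1.01.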

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

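The test of the group mix of the sets and those of scaling and set for the genes higher in MVI were chosen only after the result was seen.

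The effects of ABMR and TG against Stable differed for 23 of the named genes as deposited, by the direct limma test between the groups. Of these calls 8 (BIRC5, CXCR4, PRKCB, FRZB, WNT2B, ENG, JAG1 and TCF7L1) were kept under every alternative run for them, apart from the fits of each set alone. In the second set alone all of these 8 but FRZB fell short by limma, with adjusted p from 0.109 (JAG1) to 0.347 (BIRC5 and CXCR4). PRKCB (0.154), WNT2B (0.139) and JAG1 (0.0885) also fell short in the first set alone. The calls of the other named genes ended under at least 1 alternative other than the fits of each set alone. With only these groups in the fit, those that ended included TLR2 (adjusted p = 0.0513), SOX17 (0.0922), HMOX1 (0.123) and PPP3CC (0.135), and with the set as a covariate SOX17 (0.0718) and PPP3CC (0.0603) ended. ABMR minus TG on the log2 scale was 1.01 for BIRC5, 0.87 for CXCR4, 0.86 for PRKCB, 0.61 for TLR2, 0.54 for HMOX1, 0.48 for CEBPD, 0.47 for FRAT1, 0.38 for PPP3CC and 0.30 for CCND3. It was -1.01 for FRZB, -0.80 for FGF7, -0.79 for DKK3, -0.70 for WNT2B, -0.59 for SOX17, -0.59 for ENG, -0.58 for JAG1, -0.48 for PPAP2B, -0.47 for VEGFC, -0.45 for KDR, -0.42 for TCF7L1, -0.36 for FZD4, -0.29 for LRP6 and -0.28 for BMPR2.

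Chance is argued against as the source of each count of calls as deposited. Of 100 splits of the same biopsies, the real one included, 1 reached the real count in each comparison. That is the lowest share such splits can give, and they did not keep each group's share of the sets of columns. The real counts were 86 for MVI, 88 for ABMR and 51 for TG against Stable, where the highest other splits gave 26, 17 and 5. For ABMR against TG the real count was 24 and the highest other split gave 18. This comparison called 14 genes by Wilcoxon test, 15 with blocks of 12 columns and 13 with only those groups in the fit. Splits were not run under these alternatives.

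The genes higher in MVI have several candidate sources. Scaling is argued against as the whole source, since 39 of the 54 (72.2%) stayed higher after re-centring. The set is argued against as well, since 79 of all 86 calls in MVI were kept with the set as a covariate. Also, 100% of the 54 were higher in both sets, though their choice from the pooled biopsies favours this. A larger share of leukocytes stays open: the index of RAC2, PRKCB and CXCR4 was chosen after their changes were seen, and these genes are also measured in Stable biopsies (geometric means of 145.9, 65.8 and 248.1 normalized counts). Within Stable biopsies alone, the slope of a gene on this index tracked its MVI difference across the other genes (Spearman correlation 0.596, bootstrap 95% interval 0.327 to 0.670), and 49 of the 51 other genes higher in MVI had a positive slope, against 9 of the 32 lower genes. With the index as a covariate 0 of these 51 were called by limma, their median difference going from 0.56 (median SE 0.13) to 0.16 (0.15), but the index itself follows the group, so leukocyte number, leukocyte activity and injury may all be read by it, and SOST alone stayed called (-1.38).

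The 2 sets of columns differed in 61 genes, 35 higher and 26 lower in the second set, by a median of 0.40 and at most 2.08 on the log2 scale. The mix of ABMR, TG and Stable biopsies is argued against, since 61 genes were called with the group in the model and 61 without it, 57 of them in both. Gene factors carrying the measurement error of the repeated biopsies may contribute: the size of the set difference and the disagreement of the repeats had a partial Spearman correlation of 0.032 across genes with mean expression held fixed (bootstrap 95% interval -0.100 to 0.171), too wide to decide. No biological explanation was tested.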

How the results depend on the processing

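Alternatives on the sets, quantile normalization and re-centred camera for lists, and those on the TG library highest in COL1A2 and on shallow libraries were chosen after seeing the data. Of 1335 reruns of 90 named gene results, 1180 kept their direction and side of the threshold, 142 fell short of it, 13 newly passed and 0 changed sign. Apart from the fits of each set alone, 37 of 39 called named genes in MVI against Stable kept their call under every alternative run for them. So did 9 of 11 in ABMR, 11 of 12 in TG and 8 of 23 in ABMR against TG. The alternatives counted here were 13, or 12 for the genes that leaving out the lowest genes removes (7 of the 37, 2 of the 9, 1 of the 11 and 1 of the 8).

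Re-centring and quantile normalization moved the balance of calls; the cause was not tested. Quantile normalization called 44 genes higher and 61 lower in MVI, 36 and 58 in ABMR, 28 and 34 in TG, and 10 and 10 in ABMR against TG. Re-centring called 78 genes in TG (27 higher, 51 lower) and 11 and 9 in ABMR against TG, where robust limma called 6 and 27. It turned the TCF/LEF (adjusted p = 1.3e-04) and planar cell polarity (0.0213) lists in TG down from an uncalled upward direction, as did quantile normalization (0.0123 and 0.0421), and called 9 lists in ABMR (5 as deposited) and 1 in ABMR against TG (4 as deposited). With an estimated correlation and quantile normalization the TCF/LEF and planar cell polarity lists in TG had adjusted p = 0.429 and 0.548. By fry, quantile normalization called 8 lists in MVI, ABMR and TG each and 2 in ABMR against TG.

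The first set alone called 30 genes in MVI, 57 in ABMR and 2 in TG, and the second set alone 28 in TG and 4 in ABMR against TG. A limma test of whether group differences changed between the sets called 0 genes in each comparison. Its lowest adjusted p was 0.131 in ABMR and 0.673 in TG, which does not show that the differences are equal. The cause of the unlike counts was not tested further. ABMR against TG gave 14 genes by Wilcoxon test, 15 with blocks of 12 columns and 13 with only those groups in the fit; the cause was not tested. Camera called 0 lists in MVI, ABMR and TG against Stable and 1 in ABMR against TG with the preset correlation, and 0 in each with an estimated one, also with the set as a covariate. With re-centring the estimated correlation left 0, 0, 0 and 1; camera compares a list with the other genes, which fry does not. In TG 2 lists, target genes and endothelial genes, passed with the set as a covariate. In ABMR against TG 1 passed with blocks and 2 without the TG library. Scaling to housekeeping genes and DESeq2 were not run, as the table holds no such genes and no raw counts. Depth is known for the second set only; without its 4 libraries under 30000 counts, 84, 85, 47 and 26 genes were called in the 4 comparisons.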

Other observations

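Toll-like receptor genes were part of no fixed list, and all but TLR2 were chosen after their values were seen. In MVI against Stable, limma called TLR1 higher by 0.91 ± 0.11 (log2, SE; above the Stable mean in 45 of 48 MVI biopsies), TLR2 by 1.10 ± 0.14 and TLR4 by 0.60 ± 0.10, while TLR3 did not pass (-0.01 ± 0.10, adjusted p = 0.919). Among VEGF ligands and receptors, also chosen after their values were seen, the co-receptor NRP2 (0.51 ± 0.12) and the ligand VEGFC (0.29 ± 0.11) were higher as deposited (VEGFC not after re-centring, adjusted p = 0.284), and FLT4, the receptor of VEGFC, was lower (-0.28 ± 0.11) beside VEGFA, FLT1 and KDR. The co-receptor NRP1 did not pass (0.16 ± 0.10, adjusted p = 0.192).

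One TG library stood apart from all others, with a COL1A2 value of 843158 normalized counts against a median of 5068 in the other libraries and a highest of 300077. Its SFRP4, MMP2 and TWIST1 values were 97.4, 61.2 and 58.9 times the median of the others, and its CDH1 value of 30.5 lay below the lowest of the others, 370.6. In all, 5 libraries had COL1A2 over 90000, 1 ABMR, 1 TG and 3 Stable.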
